A study of Sus scrofa with 16 samples.

How the data were processed

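Total RNA from left ventricle was labelled with biotin and hybridised to a one-channel Affymetrix porcine array, per the labels' protocols, with 1 array for each of 16 pigs. The values used are log2 signals per probe set as deposited by the authors. The method of summarisation and normalization is not given in the sources used here. Unit and scale were read from the values, which ran from 2.87 to 14.86 and had closely matching distributions on all arrays, with medians from 6.236 to 6.242, so no further normalization was applied. Scanner files were not used here. The number of arrays limits the precision of every comparison.

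Groups of 8 exercised and 8 sedentary animals, with 4 females and 4 castrated males in each, came from the labels. Of 24123 probe sets, 188 Affymetrix controls were left out, and 23935 were tested. Gene symbols came from the platform annotation, which can be old. Of its 10297 entries, 9989 matched the RefSeq table of assembly Sscrofa11.1 by Entrez identifier, which changed 0 symbols and was used for names only. A single symbol was given for 10069 of the probe sets tested, several for 198 and none for 13668, and no gene was named from a probe set with several.

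A linear model with a mean for each of the 4 combinations of training and sex was fitted to all 16 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3. It left 12 residual degrees of freedom, and eBayes added 3.50 prior degrees of freedom. The contrasts were the training effect averaged over the sexes, the training effect in each sex, the difference between those effects, and the sex difference averaged over training. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p, without a limit on fold. Every adjusted p for a gene is from limma. In the text, rose, fell, higher and lower for a gene in a training comparison mean exercised relative to sedentary animals.

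For 39 lists of genes, camera of limma was run with a preset correlation between genes of 0.01 on the brightest probe set per gene, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a common direction, were alternatives. Counts of members past the threshold are given over all probe sets and adjusted over the list alone. The level of a list on an array is the mean of its genes' deviations from their means over the 16 arrays. Levels and array measures were compared by two-sided exact permutation tests over the 12870 assignments of 16 arrays to groups of 8 and 8.

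The gene lists, the contrasts, the tests and the rule for named genes were fixed before the data were examined. That rule took, per contrast and gene symbol, the probe set with the smallest p. For training it named the 12 largest rises and the 12 largest falls past the threshold. For the sex difference it named up to 10 per direction and the measured sex-linked genes that had been listed, and for the other contrasts 5 per direction, or the 3 smallest p values per direction where none passed. It also named a set of cardiac genes always, and up to 4 members with the smallest p of each list described. Text states where other probe sets of a gene moved the opposite way at an unadjusted p under 0.05, and where the value is not from the gene's brightest probe set. A second rule, chosen after the values were seen, named the 12 largest rises and falls above the 60th percentile of mean level, 6.88 log2. Of the genes these rules name, 2 are not reported here.

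Array quality was checked by the correlation of each array with the mean of the others, by Affymetrix controls and by principal components. The 39 poly-A control probe sets, for bacterial transcripts that are spiked in before labelling, parted the arrays into the 2 batches used as a block or apart, a choice made after the data were seen. Alternatives were quantile normalization, median centring, filters on dim probe sets at the 40th and 60th percentiles, a trended and robust eBayes, array weights, a block for the replicate number, and the first principal component of the residuals as a covariate. Others were a fold limit of 0.5 log2, an adjusted p of 0.1, no sex term, the mean of all probe sets of a gene, and leaving out each array in turn.

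The fits were tested on simulated data of 23935 probe sets in which 200 were changed. Each probe set had independent normal noise with its own residual spread, without batches or correlation between genes. The shares below therefore do not measure false calls in the real data. For the training effect 62% of changes of 0.5 log2 and 96% of changes of 1 log2 were recovered, and 4.82% of calls were false. In females these shares were 37% and 85%, and in males 34% and 76%. For the interaction they were 8% and 54%, and for the sex difference 69% and 94%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.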

Results

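Transcript levels were measured in left ventricular tissue from 16 young pigs on a one-channel Affymetrix porcine array, with 1 array per animal. There were 8 animals in the exercise-trained group and 8 in the sedentary group, each with 4 females and 4 castrated males aged 2 to 3 months. Tissue was taken 4 to 5 weeks after the start of the protocol. The table held 24123 probe sets, sets of short DNA probes against the same transcript, with values from 2.87 to 14.86 on the log2 scale. Of the 23935 probe sets tested, 10069 carried a single gene symbol, for 6765 distinct genes. Each array correlated with the mean of the others at 0.988 to 0.994 across probe sets.

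The arrays fell into 2 batches that the labels do not name. The bacterial poly-A control transcripts averaged 8.12 ± 0.36 (SD) log2 on 11 arrays, batch A, and 6.35 ± 0.22 on 5 arrays, batch B. The same split appeared in the gap between 3' and 5' probe sets for actin, at 2.625 log2 in batch A and 1.501 in batch B. It did not appear in that gap for GAPDH, at 0.302 in batch A and 0.304 in batch B. Batch A held 6 exercised and 5 sedentary animals. Batch B held exercised 7 and 8 with sedentary 6, 7 and 8, and 0 exercised females. The first principal component, with 30.1% of the variance, separated these batches. The second, with 15.7%, separated the training groups without overlap (exact permutation p = 0.000155, the smallest possible; Benjamini-Hochberg adjusted 0.0014 over 9 array measures). None of the other 8 measures differed between training groups, with the smallest exact permutation p at 0.175.

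**Figure D1:**
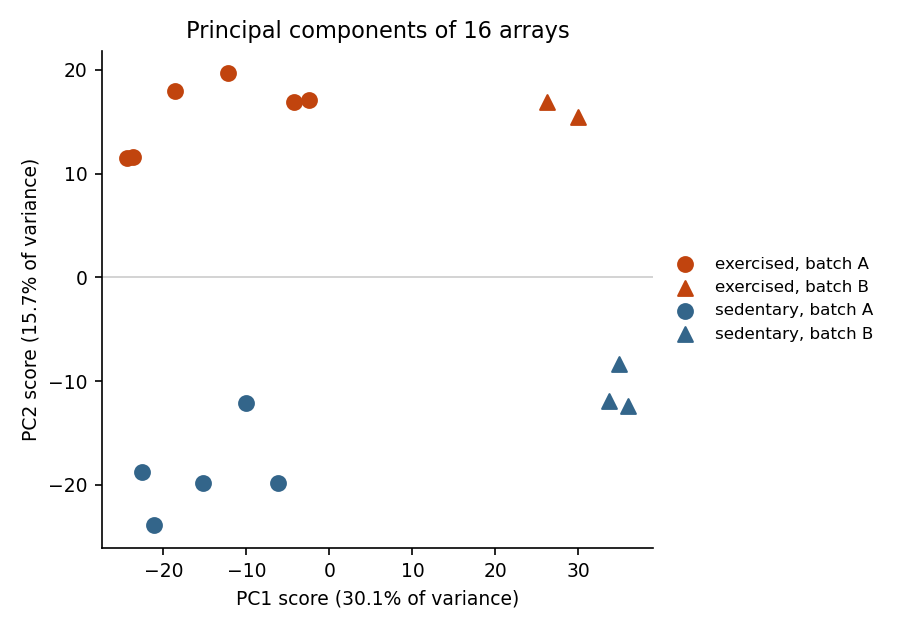
Principal components of the 16 arrays; each point is an array, coloured by training group, with circles for batch A and triangles for batch B. The first component, with 30.1% of the variance, parts the batches, and the second, with 15.7%, parts exercised from sedentary animals.

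The first comparison asked which transcripts differ between trained and sedentary hearts. NR4A3, an orphan nuclear receptor gene switched on quickly by stimuli, had the largest fall of any called named gene, to 7.35 ± 0.71 log2 in exercised animals from 9.36 ± 0.77 in sedentary animals (mean ± SD, n = 8 per group). That is a 4.02-fold difference (log2 -2.01, SE 0.353, adjusted p = 0.00162), with -1.98 in batch A and -1.88 in batch B. Differences given for a gene or a list level in batch A or B are plain differences of group means, not averaged over the sexes. They are therefore not on the same footing as the main effect. OXCT1, which codes for the mitochondrial enzyme that commits ketone bodies to oxidation, rose to 10.37 ± 0.18 from 9.44 ± 0.32 (log2 0.94, SE 0.117, n = 8, adjusted p = 0.000155). Its brighter second probe set changed by 0.28 and did not pass (adjusted p = 0.154). HSP70.2, an inducible heat shock protein, fell by 0.89 on a probe set that was not its brightest, to 8.75 ± 0.23 from 9.64 ± 0.57 (adjusted p = 0.00737). THBD, the endothelial anticoagulant receptor thrombomodulin, fell by 0.82 to 7.37 ± 0.28 from 8.19 ± 0.41 (adjusted p = 0.00523). Each of these 4 genes lay on the stated side of the sedentary mean in all 8 exercised animals.

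In all, 3197 of 23935 probe sets passed an adjusted p of 0.05, with 1550 higher and 1647 lower in exercised animals, covering 1062 gene symbols. At an unadjusted p under 0.05 there were 6474. Most changes were small: the median size among the called probe sets was 0.35 log2, 572 reached 0.5 and 20 reached 1. With array batch as a block 4325 probe sets passed, and within batch A alone 2456 did. Batch B alone gave 0 by limma, in a comparison of its 2 exercised with its 2 sedentary males. Its 1 sedentary female did not enter that contrast, so this count is not for the effect averaged over the sexes.

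Among the largest rises, LRP8, a lipoprotein receptor gene, was 1.32 log2 higher (SE 0.412, adjusted p = 0.045) and F3, which codes for the coagulation initiator tissue factor, 1.08 higher (SE 0.328, adjusted p = 0.0398). FXYD2, a regulatory subunit of the sodium pump, rose by 1.07 (SE 0.096, adjusted p = 1.14e-05) from 4.74 to 5.81. ATIC, an enzyme of purine synthesis, rose by 0.96 (adjusted p = 8.52e-06) from 4.15 to 5.11, while its brightest probe set changed by 0.17 and did not pass. The replication genes PCLAF and ORC1 rose by 1.06 and 0.83, with 0.46 and 0.73 in batch A and 2.03 and 0.98 in batch B. SEMA4D, a signalling membrane protein, rose by 0.94, the ceramide-cleaving enzyme gene ASAH1 by 0.90 and the cytochrome P450 gene CYP2C91 by 0.87. FAS, a death receptor, rose by 0.79 and AGTPBP1, which trims glutamates from tubulin, by 0.78.

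Among the largest falls, PTX3, a soluble pattern recognition protein, fell by 1.36, with -1.92 in batch A and -0.17 in batch B. NLN, a peptidase gene, fell by 1.21, but its brightest probe set changed by -0.05 and did not pass (adjusted p = 0.636). PDYN, an opioid peptide precursor, fell by 1.17 and the RNA-binding factor gene UBAP2L by 1.13, in 6 and 7 of the 8 exercised animals. PRKAG2, a regulatory subunit of the energy sensor AMPK, fell by 0.88 to 7.46 ± 0.38 from 8.34 ± 0.54 (n = 8, adjusted p = 0.0121), with -0.91 in batch A and -0.98 in batch B. The uncharacterised gene LOC100621607 and the centromere gene CENPI both fell by 0.85. The putative RNA-binding gene KHNYN and the lysosomal protease gene CTSC both fell by 0.83. For UBAP2L, LOC100621607, KHNYN and CTSC the brightest probe set of the gene did not pass.

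**Figure D2:**
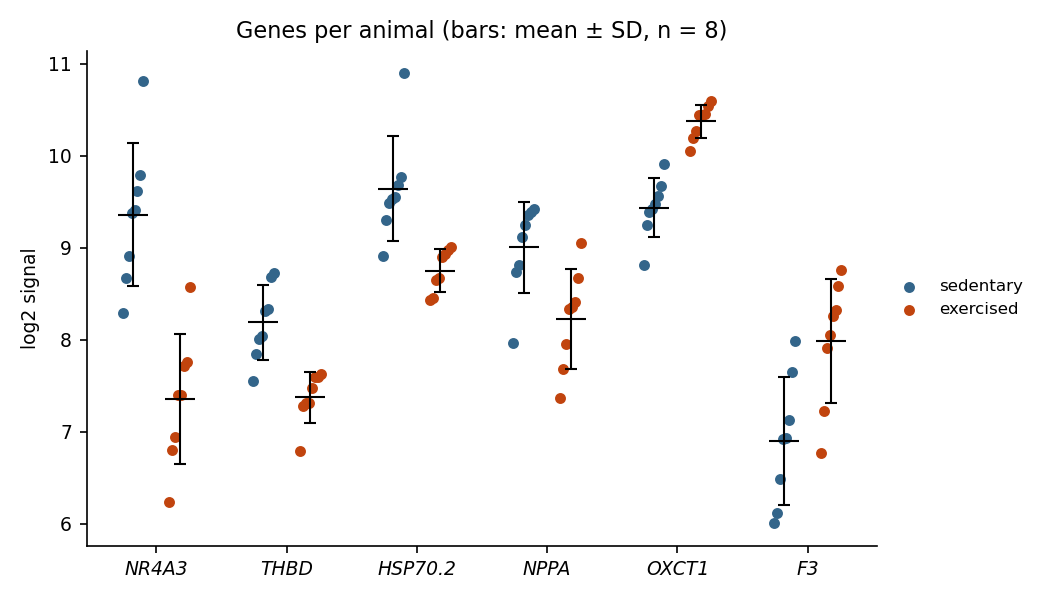
Log2 level per animal for named genes in exercised and sedentary pigs; each point is an animal and bars give the mean ± SD (n = 8 per group). NR4A3 averaged 7.35 in exercised and 9.36 in sedentary animals.

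Because 11 of these 24 largest changes lay at or below the 40th percentile of level, the largest changes above the 60th percentile were also listed, a rule chosen after the values were seen. Further rises there were in GNLY, a cytotoxic granule protein (0.69), METTL23, a methyltransferase (0.68), ATP5L, an ATP synthase subunit (0.64, not on its brightest probe set), and TRPT1, a tRNA phosphotransferase (0.61). SNRNP35, a spliceosome protein, rose by 0.58, CEP85, a centrosome protein, by 0.57 and PPP1R3B, which targets a phosphatase to glycogen, by 0.56. The mitochondrial arginase gene ARG2, the small GTPase gene RAB13 and the mitochondrial import receptor gene TOMM22 rose by 0.55, 0.53 and 0.52. NPPA, which codes for atrial natriuretic peptide, fell by 0.78 to 8.23 ± 0.54 from 9.004 ± 0.49 (n = 8, adjusted p = 0.0457), with -0.48 in batch A and -1.37 in batch B. PDLIM3, a Z-disc protein, fell by 0.77, the RNA-binding gene RBM12B by 0.70 and MSTO1, a mitochondrial distribution factor, by 0.69. HIVEP2, a zinc-finger transcription factor, fell by 0.67 on a probe set that was not its brightest, and DUSP1, a phosphatase that ends MAP kinase signals, by 0.66. With only the 9574 probe sets above the 60th percentile tested, 77 passed, and 10 of the 24 genes named by this rule were among them. OXCT1 (adjusted p = 0.0022), NR4A3 (adjusted p = 0.014), THBD (adjusted p = 0.0417) and HSP70.2 (adjusted p = 0.0491) passed there. PRKAG2 (adjusted p = 0.0707) and NPPA (adjusted p = 0.157) did not.

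Several genes often followed in cardiac growth did not pass. NPPB, the B-type natriuretic peptide gene, changed by -0.36 (SE 0.461, n = 8, adjusted p = 0.683), with -0.77 without exercised 2 and -0.12 without exercised 6, and the beta myosin heavy chain gene MYH7 by 0.03 (adjusted p = 0.713). ATP2A2, the calcium pump of the sarcoplasmic reticulum, changed by 0.16 and its inhibitor PLN by -0.10, both on probe sets that were not the gene's brightest. PPARGC1A, a coactivator of mitochondrial genes, changed by -0.21, the angiogenic factor gene VEGFA by -0.28 and the endothelial nitric oxide synthase gene NOS3 by -0.13. COL3A1, a fibrillar collagen, changed by -0.25 (SE 0.0919, adjusted p = 0.0811). PPARGC1A passed without sedentary 5, at -0.33 (adjusted p = 0.0283), and COL3A1 without exercised 8, at -0.31 (adjusted p = 0.0268). Leaving out 1 array, PPARGC1A reached -0.15 at the other end, VEGFA ran from -0.37 to -0.18 and NOS3 from -0.21 to -0.02. ATP2A2 ran from 0.09 to 0.22 and MYH7 from 0.01 to 0.04 in these fits, without passing. ACTA1, MYH6 and COL1A1 were not named on the array table used here.

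Of 39 gene lists, tested on the brightest probe set of each gene, 5 passed camera with its preset correlation. With array batch as a block 3 did, 1 higher and 2 lower. Immediate early genes, transcription factors and regulators induced within an hour or so of a stimulus, moved furthest, with a median of -0.36 over 25 measured genes (adjusted p = 0.00152). None rose, 5 fell and 20 did not pass; adjusted over the list alone, 0 rose and 8 fell. KLF4 fell by 0.64 (adjusted p = 0.00063) and KLF2 by 0.29 beside NR4A3 and DUSP1. The mean level of the list was lower by 0.44 in exercised animals (exact permutation p = 0.0149, Benjamini-Hochberg adjusted 0.194 over 39 lists). That difference was -0.61 in batch A and 0.01 in batch B. The list did not pass with an estimated correlation (adjusted p = 0.826 with an estimated correlation).

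Glucocorticoid-responsive genes had a median of -0.22 over 18 genes (adjusted p = 0.0443), with 0 higher, 2 lower and 16 not passing; adjusted over the list alone, 0 rose and 1 fell. DUSP1 and the transcription factor gene CEBPD fell by 0.66 and 0.64, and glutamine synthetase, GLUL, fell by 0.32 on a dimmer probe set. Heat shock and unfolded protein response genes had a median of -0.08 over 32 genes (adjusted p = 0.0443), with 2 lower and 30 not passing; adjusted over the list alone, 0 did. Here HSP70.2 fell by 0.61 on its brightest probe set (adjusted p = 0.0258). The constitutive chaperone gene HSPA8 fell by 0.57 to 3.82 log2 on a dim probe set and changed by -0.14 without passing on its brightest. HSP90AA1 went up by 0.27 on a probe set that was not its brightest, and the brightest changed by -0.12 without passing. CANX, a lectin chaperone of the endoplasmic reticulum, fell by 0.42 on a dim probe set, and 2 of its other probe sets moved the opposite way. These lists had an adjusted p = 0.826 with an estimated correlation, and list levels differed by -0.31 in batch A and 0.02 in batch B for glucocorticoid-responsive genes, and by -0.15 and -0.02 for heat shock genes.

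Cell cycle genes had a median of 0.24 over 33 genes (adjusted p = 0.014), with 3 higher, 1 lower and 29 not passing; adjusted over the list alone, 5 rose and 1 fell. The replication helicase genes MCM3 and MCM5 rose by 0.57 and 0.42, and the mitotic kinase gene AURKA by 0.38 on a dimmer probe set. MCM2, of the same helicase, fell by 0.35, while another of its probe sets moved the opposite way. Interferon response genes had a median of 0.33 over 23 genes (adjusted p = 0.0183), with 2 higher, 0 lower and 21 not passing, and the same counts adjusted over the list alone. The exonuclease gene ISG20 rose by 0.43 and the transcription factor gene IRF7 by 0.40. TAP1, a peptide transporter for antigen presentation, rose by 0.25 on a dim probe set, with another probe set the opposite way, and IFI44L changed by 0.69 without passing (adjusted p = 0.0524), also not on its brightest. Without exercised 2, whose level on this list was 1.03, the median was 0.17 and the list did not pass (adjusted p = 0.167). Both lists had an adjusted p = 0.826 with an estimated correlation. Without sedentary 8 the cell cycle median was 0.11 (adjusted p = 0.0663) and without sedentary 7 it was 0.15 (adjusted p = 0.0506), neither passing. The cell cycle difference was 0.03 in batch A and 0.56 in batch B, and the interferon difference 0.16 and 0.39. Their levels per array gave exact permutation p = 0.0852 and p = 0.121.

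**Figure D3:**
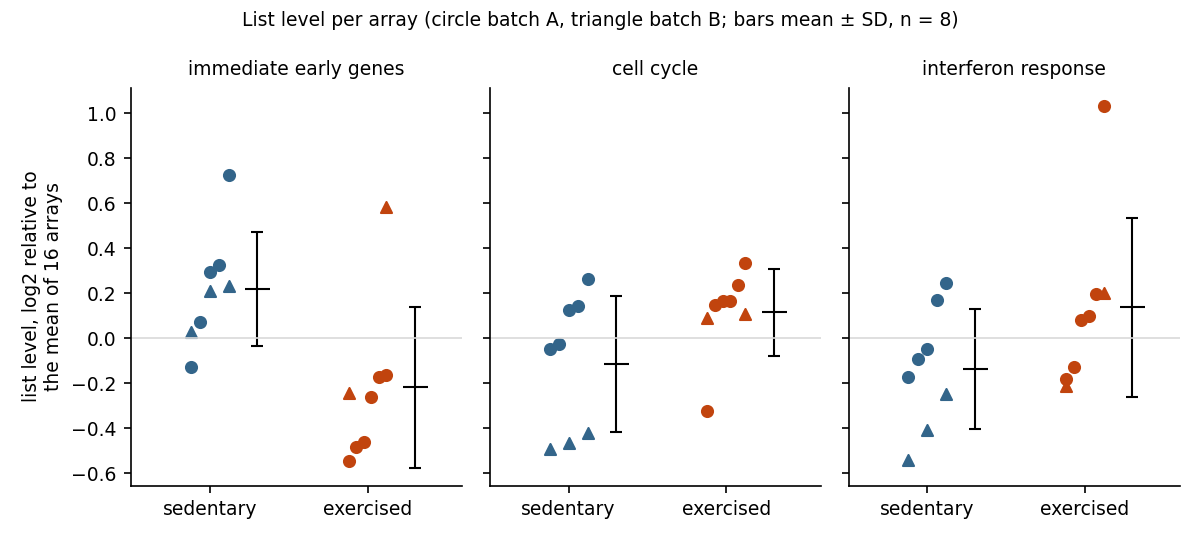
Mean level of the immediate early, cell cycle and interferon lists per array, in log2 relative to the mean of the 16 arrays, with circles for batch A, triangles for batch B and bars for mean ± SD (n = 8 per group). The immediate early gene list was lower by 0.44 on average in exercised animals, with exercised 7 apart from its group at 0.58.

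The remaining 34 lists did not pass camera. Hypertrophy and fetal genes had a median of -0.15 over 17 genes (adjusted p = 0.153), with 0 higher, 2 lower and 15 not passing; adjusted over the list alone, 0 rose and 3 fell. NPPA and the calcineurin inhibitor gene RCAN1, at -0.47, were the 2 that fell, and XIRP1, an intercalated disc protein gene, changed by -0.89 without passing (adjusted p = 0.0575). ANKRD1, a stress-responsive sarcomere gene, changed by -0.28 (adjusted p = 0.187). This list had an adjusted p = 0.826 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.05 over 55 genes, with 1 higher and 54 not passing; adjusted over the list alone, 0 did. On dimmer probe sets ATP5L, NDUFS6 and NDUFS3 rose by 0.64, 0.30 and 0.23. NDUFA1, in the same respiratory complex as both NDUFS genes, fell by 0.44 on a probe set whose brighter sibling rose.

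Antioxidant genes had 2 higher, 1 lower and 32 not passing among 35, with the same calls in number adjusted over the list alone. The glutathione enzyme genes GCLC and GSR rose by 0.65 and 0.31, and GSTA1 and GSS fell by 0.23 and 0.35; a further GCLC probe set moved the opposite way, and the GSS value was not from its brightest. Extracellular matrix genes had 1 higher, 1 lower and 36 not passing among 38, and as many adjusted over the list alone. The matrix proteases moved apart, with MMP14 lower by 0.68 on average (log2 -0.68, adjusted p = 0.000218) and MMP9 higher by 0.44 (adjusted p = 0.001). CILP, a matrix protein, fell by 0.58 and the collagen gene COL8A1 rose by 0.22 on dim probe sets, and another COL8A1 probe set moved the opposite way. Calcium handling genes had 1 lower and 15 not passing among 16; adjusted over the list alone, 0 did. The inositol trisphosphate receptor gene ITPR1 fell by 0.22. The ryanodine receptor gene RYR2 rose by 0.41 and its partner FKBP1B fell by 0.32 on dim probe sets, and the brightest probe sets of both did not pass. CACNB2, a calcium channel subunit gene, changed by -0.13 without passing. Circadian clock genes had 1 lower and 7 not passing among 8; adjusted over the list alone, 2 fell. The repressor gene NFIL3 fell by 0.49, while CSNK1D, PER1 and CRY2 changed by -0.29, -0.23 and -0.30 without passing, PER1 not on its brightest probe set. Lymphocyte markers had 2 higher, 1 lower and 10 not passing among 13; adjusted over the list alone, 3 rose and 2 fell. The T cell gene CD3G rose by 0.56 and the B cell gene CD79B by 0.26, while the cytokine receptor gene IL7R fell by 0.23. CD4 rose by 0.34 on a dim probe set, with the other probe set the opposite way.

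The share of called probe sets depended on their level. Of the called probe sets, 2027 (63.4%) lay at or below the 40th percentile of mean level, 5.57 log2. The named training calls there were FXYD2, ATIC, SEMA4D, ASAH1, CYP2C91, ORC1, FAS, PTX3, NLN, UBAP2L, CENPI, KLF2, MCM3, AURKA, ISG20, TAP1, HSPA8, CANX, NDUFS6, GCLC, CD4, CD79B, CD3G, IL7R, CILP, MMP9, COL8A1, FKBP1B, RYR2 and ITPR1. Within a sex, TSTD1, PUM2 and RAB19 also lay there, as did LOC396706 between the sexes. With the probe sets ranked by level into 10 bins of equal size, 26.6% and 26.1% passed in bins 3 and 4, against 3.17% in the brightest bin. At an unadjusted p under 0.05 the share peaked at 44.5% in bin 3, while for the difference between the sexes it ran from 2.63% to 13.04%. Above the 60th percentile 449 of 9574 passed, with 245 higher and 204 lower.

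**Figure D4:**
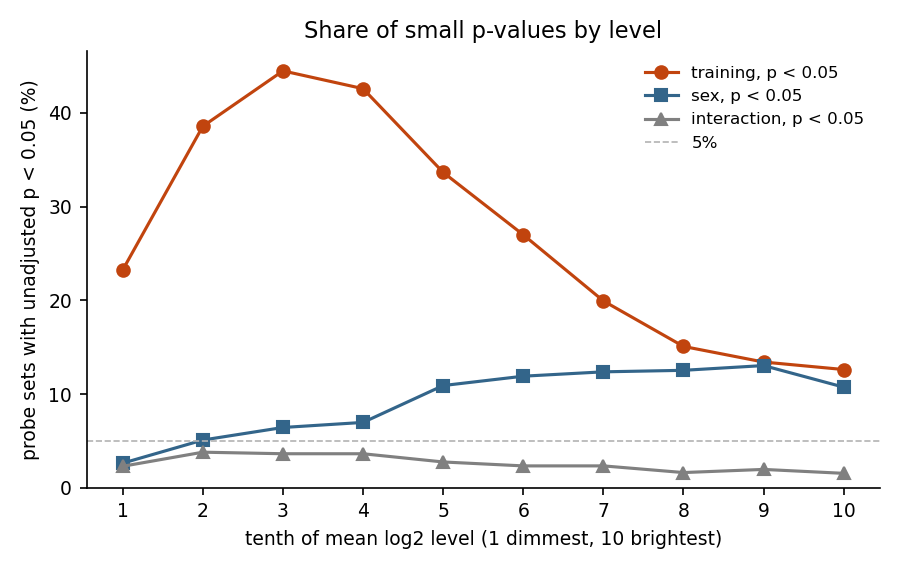
Percentage of probe sets at an unadjusted p under 0.05 in 10 bins of mean log2 level, from dimmest to brightest, for training and for sex. The share for training peaked at 44.5% in bin 3 and was 12.6% in the brightest, where that for sex was 10.7%.

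The next comparisons asked whether training acted alike in females and castrated males. In females NR4A3 fell by 2.14 to 7.28 ± 0.71 from 9.42 ± 0.38 (n = 4 per group, limma adjusted p = 0.0267), and PDLIM3 fell by 1.604 (SE 0.32, adjusted p = 0.0117). ATIC, FXYD2 and OXCT1 rose by 1.12, 1.09 and 0.98, followed by the sulfurtransferase gene TSTD1 at 0.96 and RGS10, a brake on G protein signalling, at 0.94. NLN fell by 1.22, the splicing gene SNRPA1 by 1.06, with another probe set the opposite way, and PUM2, a translational repressor, by 0.95. The values of ATIC, OXCT1, NLN, SNRPA1 and PUM2 came from probe sets that were not the gene's brightest. In total 890 probe sets passed in females, 476 higher and 414 lower.

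In males NR4A3 fell by 1.87 (SE 0.499, n = 4 per group, limma adjusted p = 0.0494) and HSP70.2 fell by 1.16 to 8.70 ± 0.30 from 9.85 ± 0.71 (adjusted p = 0.0305). FXYD2, SEMA4D, ORC1 and OXCT1 rose by 1.05, 0.94, 0.91 and 0.90, and RAB32, a GTPase of mitochondria and melanosomes, rose by 0.94. NLN fell by 1.21, KHNYN by 1.02 and the GTPase gene RAB19 by 0.87, with another RAB19 probe set the opposite way. The RAB32, OXCT1, NLN, HSP70.2 and KHNYN values came from probe sets that were not the gene's brightest. In total 902 passed in males, 390 higher and 512 lower, and 1553 passed with array batch as a block.

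Both sexes shared 215 higher and 251 lower probe sets, against 7.76 and 8.86 for independent lists, and 0 passed in opposite directions. Across all probe sets, which are not independent replicates, the effects in females and males correlated at 0.578. The difference between the effects, tested as an interaction, passed for 0 probe sets by limma, with 621 at an unadjusted p under 0.05. The smallest p values, none of them passing, were those of MUC15, a membrane mucin gene (0.85), the endosomal adaptor gene APPL2 (0.67) and the GABA-synthesising enzyme gene GAD2 (0.45). In the other direction they were PDLIM3 (-1.66), the gamma-secretase gene APH1A (-1.20) and the BMP receptor gene BMPR1B (-0.87). The APPL2 and BMPR1B values were not from the gene's brightest probe set. The PDLIM3 fall in females compares with a change of 0.06 in males.

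By camera with its preset correlation, 4 lists passed in females and 1 in males. In females these were immediate early genes (median -0.39, adjusted p = 0.000238), glucocorticoid-responsive genes (median -0.31, adjusted p = 0.000565), interferon response genes (median 0.55, adjusted p = 0.00042) and fibroblast markers (median -0.24, adjusted p = 0.0306). They had an adjusted p = 0.847 with an estimated correlation. The immediate early median in females was -0.24 without sedentary 1 and still passed (adjusted p = 0.00683). Without exercised 2 the interferon median in females was 0.25 and did not pass (adjusted p = 0.126). The fibroblast markers did not pass without exercised 6 (median -0.13, adjusted p = 0.28), sedentary 4 (adjusted p = 0.191) or sedentary 1 (adjusted p = 0.0565), and their median was -0.39 without sedentary 8. In males cell cycle genes passed (median 0.24, adjusted p = 0.00429), with an adjusted p = 0.87 with an estimated correlation, and did not pass without sedentary 7 (median 0.10, adjusted p = 0.127), sedentary 6 (median 0.16, adjusted p = 0.0588) or exercised 3 (median 0.14, adjusted p = 0.0546).

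The last comparison, between females and castrated males, also tested the labels. EIF1AY, the Y-linked copy of a translation initiation factor gene, was at 3.33 ± 0.12 log2 in females and 9.50 ± 0.24 in males (n = 8 per sex, log2 -6.17, limma adjusted p = 2.03e-16), with no overlap. The female level lay below 3.73, the median of the probe sets for sequences foreign to the pig, so background limits the size of this difference. Its X-linked partner EIF1AX was 0.44 higher in females (adjusted p = 0.00793) on a probe set that was not its brightest, and the X-linked histone demethylase gene KDM6A was 0.72 higher (SE 0.0807, adjusted p = 0.000274). TXLNG, an X-linked syntaxin-binding gene, was 0.49 higher, with another probe set the opposite way. The X-linked zinc-finger gene ZFX was lower in females (log2 -0.96, adjusted p = 0.00192), the opposite direction to EIF1AX, KDM6A and TXLNG, and what its probe set reads was not tested. The uncharacterised gene LOC396706 was also lower in females (log2 -1.08). SRY, the testis-determining gene, differed by 0.07 and did not pass, nor did the X-linked genes KDM5C (-0.06) and USP9X (0.43, adjusted p = 0.139). In total 22 probe sets passed, 13 higher and 9 lower in females, with 2217 at an unadjusted p under 0.05. Of these, 16 had no single gene symbol, including the strongest rise at 6.59 log2, where the male mean of 3.36 also lay at background. XIST and the other Y-linked genes were not named on the array table used here.

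For the sexes, 8 of 39 lists passed camera with its preset correlation, and all had an adjusted p = 0.853 with an estimated correlation. With array batch as a block 8 also passed, but 4 were higher and 4 lower in females, against 5 and 3 as reported. Sex and batch were partly mixed, since batch B held 2 exercised and 2 sedentary males, 1 sedentary female and 0 exercised females. Cell cycle genes were higher in females (median 0.26, adjusted p = 3.67e-05). Their level per array was higher by 0.25 (exact permutation p = 0.066, Benjamini-Hochberg adjusted 0.368 over 39 lists). No member passed over all probe sets; adjusted over the list alone, 4 were higher and 1 lower. CDCA3, CCNB1 and PTTG1, which act in mitosis, differed by 0.57, 0.88 and 0.67, and MCM2 by -0.30. Oxidative phosphorylation genes were lower (median -0.06, adjusted p = 0.000392), with ATP5J, NDUFV3, NDUFV1 and NDUFA12 at -0.27, -0.42, -0.19 and -0.18, none passing. Glycolysis genes (median -0.12) and tricarboxylic acid cycle genes (median -0.07) were also lower. SLC16A3, a lactate transporter, PYGM, the muscle glycogen phosphorylase, GAPDH and PKM differed by -0.50, -0.67, -0.57 and -0.14, none passing. Interferon response genes (median 0.17), extracellular matrix genes (median 0.08), endothelial markers (median 0.09) and ribosomal protein genes (median 0.03) were higher. Examples not passing were IFIT2, IFIT1 and DDX58 at 0.50, 0.52 and 0.43, ISG20 at -0.16, COL6A3 at 0.35, TGFB2 at 0.25, COMP at -0.16 and CILP at 0.71. Exercised 2, a female, stood at 1.03 for the interferon list, and without that array DDX58 differed by 0.23. The values of PYGM, GAPDH, PKM, IFIT1, TGFB2 and COMP were not from the gene's brightest probe set. Adjusted over the list alone, 0 members of these 7 lists passed. Without exercised 5 only the cell cycle and oxidative phosphorylation lists passed camera, so the calls of the other lists ended there.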

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

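The test on probe sets for sequences foreign to the pig and the test on lymphocyte markers were chosen after the results were seen.

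Single animals lay far from the others of their group in 31 of 302 groups examined, by the gap to the nearest other animal relative to the range. Chance alone gives about 1 in 20 such groups. Among exercised animals these were PCLAF at 5.87 log2, NLN at 5.24, UBAP2L at 6.41, CENPI at 4.50, THBD at 6.79, PDLIM3 at 9.10, NPPB at 10.35, KLF4 at 7.61, MCM5 at 6.45, CD4 at 3.67 and CD79B at 4.38. Among sedentary animals they were SEMA4D at 4.46, AGTPBP1 at 5.29, HSP70.2 at 10.90, ATP5L at 6.72, NPPA at 7.96, RAB32 at 6.73, APH1A at 7.63, PPARGC1A at 9.58, CD4 at 3.50 and MMP14 at 7.43. Among females they were CDCA3 at 4.49, NDUFV3 at 7.84, IFIT2 at 7.77 and DDX58 at 8.26, and among males SRY at 4.30 and NDUFA12 at 12.80. The hybridization controls of exercised 4 averaged 8.66 log2. Of the list levels, exercised 7 stood apart for immediate early genes at 0.58, exercised 5 for cell cycle genes at -0.32 and exercised 2 for interferon response genes at 1.03.

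The training effect differed between the sexes for 4 lists by camera with its preset correlation, as female minus male effect. The medians were -0.36 for glucocorticoid-responsive genes, -0.31 for inflammation genes, 0.35 for interferon response genes and -0.11 for cholesterol and lipid synthesis genes. None passed with an estimated correlation, where the lowest adjusted p over the 39 lists was 0.458. Single arrays carried part of this. Inflammation genes stood at 1.11 in sedentary 1 and 0.91 in exercised 7, and the difference was -0.10 without the former (adjusted p = 0.345), -0.16 without the latter (adjusted p = 0.21) and -0.19 without exercised 6 (adjusted p = 0.0573). The interferon difference was 0.13 without exercised 2 (adjusted p = 0.582), 0.30 without sedentary 8 (adjusted p = 0.148) and 0.26 without sedentary 5 (adjusted p = 0.0614). The cholesterol list did not pass without exercised 6 or sedentary 2, 7 or 8, with an adjusted p from 0.0539 to 0.109, and its difference was -0.17 without exercised 1 and -0.07 without exercised 8. The glucocorticoid list passed in all 16 fits that left out an array, with -0.24 without sedentary 5.

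Many dim probe sets passed for training. Of the 100 splits within sex, 1, the real one, called as many probe sets of all levels (3197 against at most 1451), which argues against chance. If changed transcripts of the named genes were the whole cause, the brightest other probe set of a gene would move with the called dim one. It did for 52.8% of 324 genes (95% exact interval 47.2 to 58.3), against 72.8% of 114 genes called on bright probe sets (63.7 to 80.7), which argues against it; where the other probe set of a dim call was itself called, 26 moved the same way and 9 the opposite way, much as for bright calls (11 and 5), so a changed transcript stays open for such genes. Of 87 probe sets for sequences foreign to the pig, 20 (23.0%) had an unadjusted p under 0.05 for training, against 31.7% of porcine probe sets of like level, while for sex these shares were 3.45% and 4.25%. A difference between the groups in how their arrays were processed may therefore account for part of the dim calls; cross-hybridising transcripts that changed with training were not tested and also stay open.

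Immediate early genes were lower in exercised animals, and 1 of 100 splits within sex, the real one, moved the list mean as far (0.438 against at most 0.411). The list was singled out as the one that moved furthest, and the splits do not allow for that choice. The second probe sets of these genes were lower in 11 of 14 cases (78.6%, 95% exact interval 49.2 to 95.3). They came from 8 genes, and the interval treats probe sets of the same gene as independent, so it understates the uncertainty. This leaves open whether a difference in array processing could contribute. Without exercised 3 and 5 and sedentary 1 and 2, the lowest exercised and highest sedentary arrays, the median was -0.0813, but removing arrays that favour the fall shrinks any difference, and without exercised 7 it was -0.51, so this does not decide whether a few animals carry the fall. In batch B the list did not differ (0.01), where exercised 7, at 0.58, was 1 of 2 exercised animals, and sedentary 1 and exercised 7, the highest for this list at 0.72 and 0.58, were also the highest for inflammation genes (1.11 and 0.91) and erythrocyte markers (0.63 and 0.74). Training itself, and the time between the last exercise and sampling, which is not given in the sources used here, stay open as untested explanations.

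Cell cycle and interferon response genes were higher in exercised animals by camera with its preset correlation only. The larger exact permutation p of their levels per array was 0.121, so a few animals may carry these shifts, among them exercised 2 for interferon genes. For cell cycle genes the 3 sedentary animals of batch B were the lowest of all, and the difference was 0.03 in batch A. More lymphocytes in the exercised hearts could also raise such genes, but the lymphocyte markers changed by 0.14 on average (SE 0.0963 over 13 genes), which leaves this open, and training itself was not tested apart from these.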

How the results depend on the processing

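The alternatives with array batch and the filter at the 60th percentile were chosen after the data were seen. Where no construction is named, the cause was not tested.

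Quantile normalization, median centring, and the trended and robust eBayes left all probe set counts within 1.5 times those reported. Above the 40th percentile of level, where fewer and brighter probe sets were tested, 631 passed for training, 85 in females and 56 in males, where the higher share was 30.4% against 43.2% as reported. Above the 60th percentile 77 passed for training and 5 for sex. With a fold limit of 0.5 log2 the counts were 572, 471 in females and 437 in males, and at an adjusted p of 0.1 they were 1670 in females and 1634 in males, by construction. Array weights gave 2387 in females and 40 for sex. The first residual component as a covariate lowers only residual spread, by construction. It gave 1916 in females, 1666 in males and 1072 for sex. The interaction stayed at 0 in every alternative run.

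With array batch as a block 1553 passed in males, and KDM5C turned to 0.0732 for sex. For training 3 lists passed, 1 higher and 2 lower, against 2 higher and 3 lower as reported. Within batch A alone 10 lists passed for training and 15 for sex, and the cell cycle list turned to -0.0125 for training. Within batch B alone 0 passed for training, between its 2 exercised and 2 sedentary males only.

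Replicate numbers did not pair the animals. Of 8 pairs, 5 had a correlation over 0.1, but 0 with array batch removed (-0.33 to 0.05). Only 1 number was matched best by its own partner, and 2 joined animals of different sex. With that block only those 2 numbers inform on sex, too few to test it. The block gave 3528 for training, 333 in females, 402 in males and 13 for sex. For sex 5 lists passed, 0 higher and 5 lower in females, against 5 and 3 as reported. SRY turned to -0.0039, KDM5C to 0.38, NDUFA12 to 0.0238, COL6A3 to -0.0444 and the oxidative phosphorylation list to 0.0191, none passing.

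For lists, the estimated correlation gave 0 for training and 0 for sex, fry 0 and 1, and the mean of all probe sets of a gene 4 and 3. That mean gave 579 gene symbols for training, 569 of them among the 1062 reported.

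Leaving out 1 array gave 2513 to 3108 for training, 462 to 890 in females, 471 to 1010 in males, 20 to 83 for sex, 2 to 6 lists for training and 2 to 10 for sex. In females the count was 462 without exercised 1, 505 without exercised 4, 591 without exercised 6, 538 without sedentary 1, 507 without sedentary 2 and 564 without sedentary 4. In males it was 471 without sedentary 3, 522 without exercised 7 and 593 without exercised 8, with a value between those 2 without sedentary 5. For these sexes each such fit has 3 animals in an arm, by construction. The sex count was 83 without sedentary 8, the only female of batch B. All of batch B was then male, so this count cannot be told apart from a batch difference. For lists, 3 passed for training without exercised 3, sedentary 1, sedentary 2 or sedentary 3, and 2 without sedentary 7; for sex, 2 passed without exercised 5, 4 without exercised 2 or sedentary 5, and 5 without exercised 4. KDM5C ranged from -0.17 to 0.0028.

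Among genes and lists past the threshold, 1617 of 1888 values without an array stayed past it, 271 did not and 0 reversed. The call of NPPA ended in 13 of the 16 fits, those of CEBPD in 13, LRP8, UBAP2L, RCAN1 and NFIL3 in 12, F3 and ITPR1 in 11, and PDLIM3, ARG2 and COL8A1 in 10, each with an adjusted p of at most 0.0971. HSP90AA1 lost its call in 9, LOC100621607 and GSS in 8, and ASAH1 and DUSP1 in 7. IRF7 and GSTA1 lost theirs in 6, PCLAF, PDYN and GNLY in 5, and GSR in 3. Within a sex, RAB32 in males lost its call in 7, SNRPA1 and PUM2 in females in 6 and 5, and HSP70.2 in males in 3. NR4A3 passed in all 16 for training; in females its call ended in 5, with an adjusted p up to 0.0893, and in males in 13, with an adjusted p up to 0.124. Above the 40th percentile it did not pass in females (adjusted p = 0.0681) or males (adjusted p = 0.121). Of the lists, immediate early genes passed for training in all 16, cell cycle genes in 14, interferon response genes in 11, glucocorticoid-responsive genes in 10 and heat shock genes in 9. The interferon call ended without exercised 2 or 7 or sedentary 6, 7 or 8 (adjusted p up to 0.167), the glucocorticoid call without exercised 2 or 3 or sedentary 1, 2, 3 or 7 (up to 0.145), and the heat shock call without exercised 1, 3 or 4 or sedentary 1, 2, 3 or 5 (up to 0.133). The heat shock median was -0.12 without sedentary 6. With the filter at the 40th percentile 44 of 68 stayed past the threshold, and 24 did not. The linear-scale alternative was not run because the values are already log2. Signal over background limits what dim probe sets can show, since no detection measure per probe set was used here.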

Other observations

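Of the splits reported here, only that for the interaction was written down after its outcome was seen. The dim probe sets and the immediate early genes were singled out from the results of the comparisons, and their splits do not allow for that choice.

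In females the real split was the only 1 of 35 to call as many probe sets (890 against at most 1), which argues against chance. Of the splits of the males, 2 of 35 did, so the splits alone do not exclude chance there. The males' calls shared 215 higher and 251 lower probe sets with those of the females, which are separate animals. None, 0, passed in opposite directions, which argues against chance, although probe sets are not independent. The 7.76 and 8.86 for independent lists understate the overlap by chance. Both tests share the spread of each probe set, and 632 of 890 and 639 of 902 calls lay at or below the 40th percentile of level. The other split called 1978, where the remaining splits called at most 1, and set the 4 males of batch B against the 4 of batch A, which points to a structure of the samples that follows the batch. With array batch as a block 1553 probe sets passed in males. For the interaction, 100 of 100 splits reached the real count of 0, as any split must, so this comparison decides nothing about chance. The highest other count was 179.

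For the sex difference 3 of 100 splits within training group called as many as the real 22. The others called 2156 and 2282 and kept the 5 arrays of batch B together, which points to a structure of the samples that follows the batch. The count alone does not exclude chance, while EIF1AY separated the sexes without overlap. With array batch as a block 19 probe sets passed for sex. For the number of lists, 46 of 100 splits gave as many as the real 5 for training, with up to 17, and 22 of 100 as many as the real 8 for sex, with up to 20, so chance cannot be excluded for these counts.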
